A study of Mus musculus with 5 samples.

How the data were processed

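Polyadenylated RNA of 5 mouse cell cultures was measured on 1 Affymetrix expression array each. Per the labels' protocols, cells were kept in log phase, RNA was extracted with Ultraspec, messenger RNA was selected on oligo dT and the biotin labelling followed the maker's instructions. The deposited table holds 1 linear intensity per probe set and array, all above 0. Per the deposited values, the authors' intensities had been scaled so that the trimmed mean of each array, with 2 percent left out at each end, was about 150. The software and any background step behind them are not given in the sources used here, and the table used here holds no detection calls. No pair of arrays held identical values. The number of arrays limits the precision, and no array was repeated on the same culture.

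The table lists 12488 probe sets, of which 66 maker's control probe sets were left out of all tests. Gene symbols came from the array annotation of 2016, updated through gene identifiers to current mouse symbols. Of all probe sets, 10855 had 1 symbol, 396 had several and 1237 had none, and 16 symbols were kept as the annotation gave them. No gene was named from a probe set with several symbols. Where a gene had several probe sets, the one with the highest mean log2 value was used, which gave 6638 genes.

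A rule fixed before the data were examined kept the authors' scaling only if all array medians lay within 10 percent of their mean. The A20 median lay at -11.55 percent, so arrays were quantile normalised. Levels in the text are quantile-normalised intensities unless called deposited. Differences are on the scale of log2(intensity + 6.55), where 6.55 is the 20th percentile of all values. This scale understates the change of dim probe sets. Kept were 9107 probe sets whose highest value exceeded 21.8, the 40th percentile.

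Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) over all 5 arrays with 3 coefficients: the 2 hnRNP-F clones, the 2 AxJ controls (empty vector and hnRNP-H) and A20. This leaves 2 residual degrees of freedom, moderated by a prior of 6.46. Probe sets of equal rank on several arrays take equal values under quantile normalisation, which hides their spread. The difference between the controls counts as spread, and the single A20 array is assumed to vary like the AxJ arrays. All p-values are two-sided, with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. The labels name the hnRNP-F arrays as separate subclones, but nothing describes repeated cultures, so p-values measure only the spread between these arrays. With 2 arrays against 2, no exact test of a single value can go below a p of 1 in 3. For hnRNP-H against empty vector and for clone D6 against clone B5, each with 1 array a side, no test was made.

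Also fixed in advance were 25 gene lists, covering RNA processing, transcription elongation, B cell and plasma cell genes, antigen presentation, secretion, stress, metabolism, cell cycle and markers of other cell types. The 22 lists with at least 5 measured genes were tested with camera in limma at an inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. With an estimated correlation camera takes its p-values from the 2 residual degrees of freedom, so that setting has little power. A call lost there does not by itself show that the genes of a list move together. Without replicates, a list was placed by the percentile of its median among 10000 random lists matched on mean expression. The named genes followed a fixed rule. For the hnRNP-F clones these were the 10 highest and 10 lowest past the threshold with both clones on one side of both controls, and for A20 the 12 highest and 12 lowest past the threshold and outside the range of all 4 AxJ lines. Open places were filled by the smallest pairwise difference and described by values only. For comparisons without replicates the 5 highest and 5 lowest were named. From each list came up to 4 members past the threshold, otherwise the 2 with the largest moderated statistic. Hnrnpf, Hnrnph1, Ell2 and the immunoglobulin heavy chain probe sets were named whatever their values.

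The procedure was tested on simulated data with 200 changed probe sets among 9107. For the hnRNP-F comparison it recovered 32, 66, 86 and 100 percent of changes of 2, 4, 8 and 32-fold, and 10 of 152 calls were false. For the A20 comparison the shares were 8, 78, 96 and 100 percent, and 6 of 147 calls were false. These shares hold for 200 changed probe sets drawn with the moderated spread of the fit. With fewer changed probe sets the adjustment is stricter, so they overstate the power of a comparison where few change. Alternatives covered the pseudocount, the filter, the scaling, the spread model, the grouping in the fit, 1 probe set per gene, the estimated correlation and each AxJ array left out. Chosen after seeing the data were a block for arrays paired by Gapdh 5' to 3' ratio, comparisons within those pairs or without the arrays of low ratio, and a pseudocount of 32. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.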

Results

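The arrays compared 4 derivatives of AxJ, a mouse plasma cell line, that is, a line of the antibody-secreting stage, with A20, a mouse line labelled as memory B cells. AxJ cells carried empty vector (1 array), overexpressed the RNA-binding protein hnRNP-H (1 array) or overexpressed its relative hnRNP-F (2 arrays, subclones B5 and D6). The submitters chose clones by western blot and describe a lower ratio of secreted to membrane heavy chain mRNA in the hnRNP-F clones. The study's title places ELL2, a transcription elongation factor, in the choice between splicing and polyadenylation of the heavy chain gene. Median deposited intensities were 41.7 for empty vector, 37.6 for hnRNP-H, 39.6 for B5, 38.9 for D6 and 33.9 for A20. The 5' to 3' ratio of the Gapdh control probe sets, a sign of RNA integrity or labelling, was 0.212 for empty vector and 0.181 for B5, against 0.866 for hnRNP-H, 0.683 for D6 and 0.384 for A20.

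The overexpressed genes could be followed only in part. No probe set carried the symbol Hnrnpf. The Hnrnph1 probe set read 1454 in empty vector, 1060 in hnRNP-H, 727 in B5, 984 in D6 and 1523 in A20, so it was not higher in the hnRNP-H line than in empty vector. Where its probes lie relative to the transfected sequence is not known here, so this checks neither the label nor the overexpression.

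The first comparison asked which transcripts differ between the hnRNP-F clones and the AxJ controls. Rpl41, which encodes a small ribosomal protein, was the one probe set that passed the threshold. It rose by 5.78 on the log2 scale (SE 0.46, 2 clones against 2 controls, limma adjusted p = 0.00832). Its deposited intensities were 24275 in B5 and 16541 in D6 against 518 in empty vector and 164 in hnRNP-H, and 14165 in A20. Because it was the brightest probe set on the B5, D6 and A20 arrays, quantile normalisation set all 3 to 16516 and removed the spread between the clones. Under the authors' scaling, which keeps that spread, it rose by 6.07 (SE 0.48, adjusted p = 0.000791). No probe set fell past the threshold, and 527 of 9107 had an unadjusted p under 0.05. The Rpl41 call was lost without clone B5 (adjusted p = 0.123), without the filter on low values (0.182) and without the intensity trend (0.826), and its adjusted p ranged from 0.000234 to 0.826 over the alternatives, while its log2 difference stayed between 4.95 and 6.61. Without clone D6, which leaves B5 as the lone clone and the spread to the 2 controls, 3 probe sets passed, but Igkv6-23 and the one with no symbol were bright in B5 and not in D6, so their calls describe B5.

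With Rpl41 counted, 46 probe sets were at least 2-fold higher and 37 at least 2-fold lower in both clones than in both controls. The other ways to pair the 4 AxJ arrays gave 140 probe sets (empty vector and B5 against hnRNP-H and D6, the pairs that share a low or a high Gapdh ratio) and 73. Both clones lay on one side of both controls for 3421 of 9107 probe sets, and chance alone gives 33.3 percent. The highest by the smallest pairwise difference were Scx, a tendon transcription factor, with a log2 difference of 2.22 (SE 0.42), Id3, an inhibitor of E proteins, with 2.06 (SE 0.44), and Aldh3a1 with 1.80 (SE 0.41). They were followed by Upf2, Tbx2, Cpne6, Col11a2, Leng8 and Tcstv3, with log2 differences from 1.35 to 1.76. The lowest were the chemokine gene Ccl11 with -1.59 (SE 0.62), Msh5 with -1.90 (SE 0.54), Phxr4 with -1.72 (SE 0.44) and Pcf11, a factor of transcript cleavage, with -1.65 (SE 0.39). Lipe, Il1f5, Gjb2, Ccl22, Nfix and Rc3h2 followed, with log2 differences from -2.09 to -1.40. None of these genes passed (limma adjusted p = 0.790 for each), and a second Nfix probe set differed by 0.20. With Rpl41 counted, the dimmer side lay under 21.8 for 8 of the 10 highest and 8 of the 10 lowest genes. For those the pseudocount sets the size of the difference. Over the alternatives Id3 ranged from 1.10 to 2.35 and Ccl11 from -1.96 to -0.68.

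Ell2 read 3476 in empty vector, 2139 in hnRNP-H, 1800 in B5 and 2145 in D6, a log2 difference of -0.47 (SE 0.29, limma adjusted p = 0.795). The heavy chain genes did not pass either. Igha differed by -0.14 (SE 0.33), but by 0.13 under the authors' scaling and by 0.14 under median scaling. As deposited, Igha read 8345 in empty vector, 9534 in hnRNP-H, 10655 in B5 and 8922 in D6. Quantile normalisation took the controls to 7026 and 13968, which turned the sign. Ighm differed by 0.25 (SE 0.63), with 767 in empty vector and 1052 in B5 against 2837 in hnRNP-H and 2938 in D6, the latter pair being the arrays of higher Gapdh ratio. The 7 other Ighm probe sets kept differed by -1.499 to 0.66, 4 of them below 0. A second Igha probe set differed by 0.22, a second Igh-VS107 probe set by 0.41, and the other Ell2 probe sets by -1.36 and -0.09. Differences for Ighd (0.11), Igh-VS107 (-0.10), Ighv3-6 (0.50), Ighg3 (0.16), Ighv1-54 (0.58) and Ighv5-12 (-0.39) had adjusted p from 0.812 to 0.971. These probe sets were not matched here to the secreted or the membrane form.

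Among the gene lists, those of other hnRNP proteins and of splicing factors passed in the hnRNP-F clones, both downward and neither with an estimated correlation. That estimate was 0.288 for other hnRNP proteins but 0.00994 for splicing factors, near the preset 0.01. A higher correlation therefore does not account for the loss of the splicing call. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit. This took the unadjusted camera p of the splicing list from 0.00321 to 0.0982. Of 18 measured genes in the list of other hnRNP proteins, 16 lay below 0 and none passed alone, with a median log2 difference of -0.32 (camera adjusted p = 0.00112, none past the threshold adjusted over the list alone, but adjusted p = 0.844 with an estimated correlation). Hnrnpr differed by -1.02 (SE 0.30) and Hnrnpk by -0.94 (SE 0.27). The same list lay low in hnRNP-H against empty vector, with a median of -0.31 (percentile 1.31), and its median was 0.21 in D6 against B5 (percentile 97.0). Without clone B5 the list no longer passed (adjusted p = 0.0903). Of 32 splicing factor genes, 20 lay below 0, with a median of -0.07 and a mean of -0.26 (camera adjusted p = 0.0353, but adjusted p = 0.844 with an estimated correlation). Adjusted over the list alone, 3 genes fell, against none over all probe sets. Srsf10 differed by -1.49 (SE 0.33), but its other probe set by 0.50, and Clk1, a kinase of splicing factors, by -1.03 (SE 0.25). The splicing call was lost without B5 (adjusted p = 0.197), without hnRNP-H (0.524) and without the filter on low values (0.0558).

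**Figure D1:**
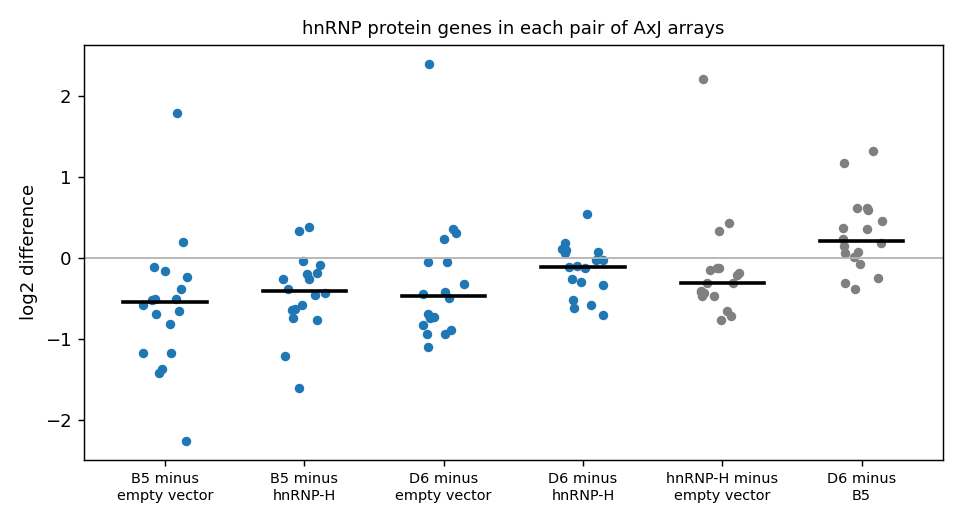
Each point is 1 of 18 genes of the hnRNP protein list, the vertical axis is the log2 difference between 2 arrays, and black bars are medians. Medians are -0.55 and -0.41 for B5, -0.48 and -0.11 for D6 (each against empty vector, then hnRNP-H), and -0.31 for hnRNP-H minus empty vector.

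The other 20 lists tested did not pass in this comparison, with camera adjusted p from 0.483 to 0.950. Among 18 genes of cleavage and polyadenylation, 10 lay below 0 (median -0.12), and Pcf11 fell when adjusted over the list alone. Among 23 genes of transcription elongation, 14 lay above 0 (median 0.06), with Nelfe at 0.52 and Ctr9 at 0.75, and 9 of 10 subunits of RNA polymerase II lay above 0 (median 0.13). The plasma cell list had a median of -0.23, with Sec11c at -0.61 and Jchain at -0.43, and the immunoglobulin list one of -0.13, with Iglc1 at -1.13 from a dim probe set. A bright probe set listed for both Iglc1 and Iglv1, not used for the list, read 11013 and 8072 in the controls and 11790 and 9929 in the clones as deposited. Of 25 B cell identity genes, 19 lay above 0 (median 0.26, adjusted p = 0.483), and Id3 rose when adjusted over the list alone. By pair, the median of this list was 0.44 and 0.19 for B5 and 0.14 and 0.03 for D6, each against empty vector, then hnRNP-H. The shift thus lay mostly in B5. In no other list did a gene pass when adjusted over the list alone. The immunoglobulin median was 0.00214 under median scaling. Medians lay between -0.22 and 0.21 for the lists of MHC class I and class II, protein folding, secretion, cell cycle, interferon, NF-kB, apoptosis, sterol synthesis, glycolysis, heat shock and silencing. Marker lists of myeloid and stromal cells had medians of -0.12 and 0.06. Signs differed for class II genes (median 0.11, mean -0.02, test lower), class I genes (median -0.03, mean 0.00347, test lower) and stromal markers (median 0.06, mean -0.02, test higher). Lists with 4 measured genes were not tested, with medians of -0.36 for the relatives of hnRNP-F and hnRNP-H, -0.02 for T cell and -0.42 for erythroid markers.

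A20 differed from the AxJ controls in B cell and plasma cell genes. Bcl6, a transcriptional repressor that acts in germinal centre B cells, was higher by 6.41 on the log2 scale (SE 0.82, limma adjusted p = 0.00369, from a control mean of 4.32 to 878). Spib, a B cell transcription factor, was higher by 5.99 (SE 0.50, adjusted p = 0.000541). The class II gene H2-Aa rose by 6.19 (SE 0.59, adjusted p = 0.000984). The heavy chain gene Igha fell by 7.24 (SE 0.40, adjusted p = 6.6e-05), from 7026 and 13968 in the controls to 58.9, and Ighm fell by 6.59 (SE 0.77, adjusted p = 0.0024). A second Igha probe set fell by 2.48 (adjusted p = 0.0132). Of the dimmer probe sets of these genes, 7 for Ighm had differences from -1.31 to 0.36 and a second one for Spib had 1.25, and none of them passed. Among gamma heavy chain genes only Ighg3 had probe sets with 1 symbol, so a heavy chain of another gamma class in A20 could not be read. The falls of Igha and Ighm therefore do not measure its total heavy chain mRNA. As deposited, Igha read 8345 and 9534 in the controls and 55.1 in A20, so quantile normalisation widened the gap between the controls. Prdm1, the plasma cell regulator Blimp-1, fell by 3.71 (SE 0.47, adjusted p = 0.00369). For 8 of the 12 highest and 8 of the 12 lowest genes named for A20 the dimmer side lay under 21.8, so that the pseudocount sets the size of the difference, which for Bcl6 ranged from 4.65 to 6.99 over the alternatives. A20 was measured on 1 array, so these differences have no replicate check on its side.

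In all, 264 probe sets rose and 272 fell in A20, and 534 of these 536 lay outside the range of all 4 AxJ lines. The count was 311 without the filter on low values and 145 without the intensity trend. It was 364 without empty vector, 667 without hnRNP-H, 245 without clone B5, 256 without clone D6 and 1709 for A20 against hnRNP-H and D6 alone, a comparison chosen after seeing the Gapdh ratios. That last count took its spread only from hnRNP-H and D6, the most alike pair of arrays (r = 0.963). A small spread between them raises the count, so it is no measure of further true differences. A20 was at least 2-fold from all 4 AxJ lines for 926 probe sets, 482 higher and 444 lower. The same count was 383 with empty vector in its place, 203 with B5, 82 with hnRNP-H and 44 with D6.

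The highest in A20 were the light chain variable gene Igkv6-23 at 8.24 (adjusted p = 0.0179), the homeobox gene Rhox5 at 8.23 (SE 1.08) and Tmsb4x, which encodes an actin-binding peptide, at 7.82 (SE 1.63). In clone B5 these read 235, 213 and 318, against at most 29.6 in the other AxJ lines. Igkv6-23 and Tmsb4x no longer passed without empty vector (adjusted p = 0.0853 and 0.141) or without hnRNP-H (0.0697 and 0.0744). Lmo7, Clca1, Prkcb, Dap, Car2 and Ltb rose by 5.78 to 6.22, but another Clca1 probe set differed by -0.23. The lowest were Trap1a at -8.05 (SE 0.28), the metallothionein genes Mt1 at -7.36 (SE 0.35) and Mt2 at -6.07 (SE 0.34), and Fkbp11, a folding factor of secretory cells, at -6.16 (SE 0.32). Csn3, Spn, Cox6a2, Tsc22d1, Zmynd11 and Dcaf8l had log2 differences from -5.95 to -4.99. Ell2 fell by 1.48 (SE 0.35, adjusted p = 0.048), and lost its call under 8 alternatives, both other scalings among them (adjusted p = 0.0581 and 0.0672). Its adjusted p was 0.0906 without empty vector, 0.122 without B5 and 0.115 without D6, and its other probe sets differed by -1.87 and -1.38 without passing. Of the other heavy chain genes, Ighg3 differed by -1.57, Ighv1-54 by 1.04, Ighv3-6 by 0.98, Igh-VS107 by 0.58, Ighv5-12 by -0.32 and Ighd by -0.20, none past the threshold. Signs turned with the probe set for Igh-VS107 (a second at -1.12) and Ighg3 (others from -1.44 to 0.60). Hnrnph1 differed by 0.29 and did not pass.

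By list, 14 of 25 B cell identity genes rose and none fell (median 2.85, camera adjusted p = 4.96e-15, but adjusted p = 0.184 with an estimated correlation), Ltb by 5.78 and Ms4a1, which encodes CD20, by 4.82. Of 14 class II and antigen presentation genes 5 rose (median 1.87, adjusted p = 0.000255, but adjusted p = 0.223 with an estimated correlation), H2-Ea by 4.87 and H2-Ab1 by 2.98. Of 15 plasma cell genes 6 fell (median -1.21, adjusted p = 5.6e-05, but adjusted p = 0.223 with an estimated correlation), Cd28 by -2.84 and Irf4 by -1.94. Of 10 immunoglobulin genes 4 fell (median -1.16, adjusted p = 0.00422, but adjusted p = 0.282 with an estimated correlation), Igll1 by -2.73 and Jchain by -1.60, though a second Igll1 probe set differed by -0.51 (adjusted p = 0.691). Light chain probe sets listed for several genes, not used for the list, parted: as deposited, one for kappa genes, Igkc among them, read 10252 in A20 against 86.9 and 36.1 in the controls, and the one for Iglc1 and Iglv1 read 418 against 11013 and 8072. Protein folding genes of the endoplasmic reticulum fell in 5 of 25 cases (median -0.75, adjusted p = 2.09e-07, but adjusted p = 0.184 with an estimated correlation), Sel1l by -3.38, Hsp90b1 by -3.07, Pdia4 by -2.62 and Creld2 by -2.51. Secretion genes fell in 8 of 34 cases (median -0.92, adjusted p = 5.03e-08, but adjusted p = 0.184 with an estimated correlation), Srp9 by -1.99, Ssr1 by -1.87, Ddost by -1.68 and Mcfd2 by -1.63, though a second Ssr1 probe set differed by -0.73 (adjusted p = 0.428). Adjusted over the list alone, 18 B cell identity and 8 class II genes rose and 1 class II gene fell, 10 plasma cell and 5 immunoglobulin genes fell and 1 of each rose, and 11 folding and 18 secretion genes fell. Of 59 named genes that passed, 15 did not without empty vector (adjusted p from 0.0511 to 0.141), 9 without hnRNP-H (0.055 to 0.109), 18 without B5 (0.0554 to 0.122) and 17 without D6 (0.053 to 0.115). Those lost include H2-Ab1, Cd28, Irf4, Igll1, Jchain, Srp9, Ssr1, Ddost and Mcfd2. For the lists, the values with an estimated correlation rest on 2 residual degrees of freedom, where even a strong shift could hardly pass.

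**Figure D2:**
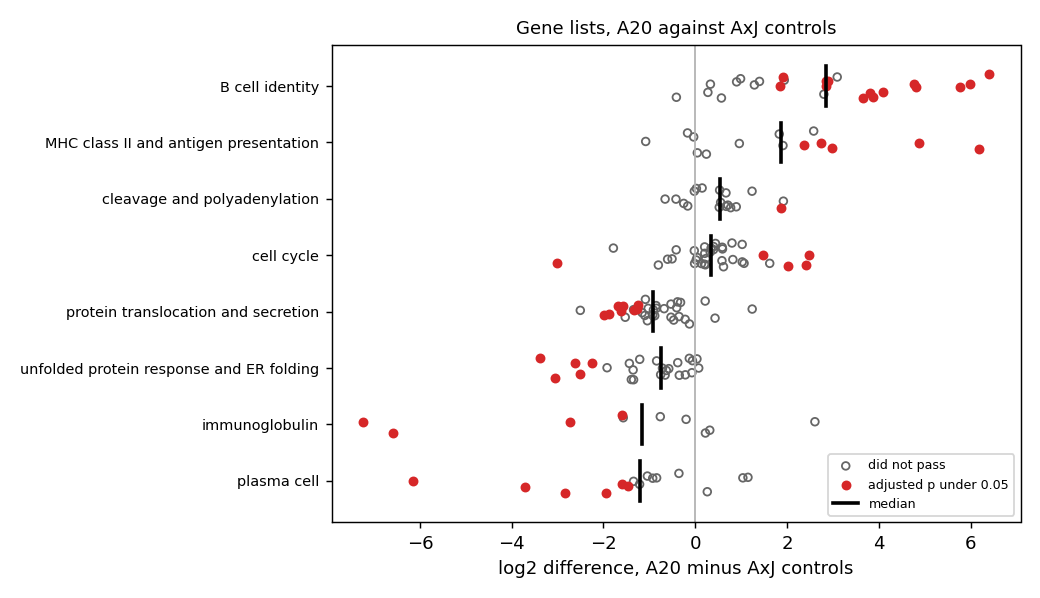
Each point is a gene of a list that passed at the preset correlation, the horizontal axis is its log2 difference between A20 (1 array) and the AxJ controls (2 arrays), filled points passed alone and black bars are medians. Medians run from 2.85 for B cell identity to -1.21 for plasma cell genes.

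Among 35 cell cycle genes, Ccnd3 (2.48), Mcm5 (2.41) and Mcm2 (2.03) were among 4 that rose, and Myc fell by 3.01 (median 0.34, camera adjusted p = 0.0217, but adjusted p = 0.308 with an estimated correlation). Adjusted over the list alone, 6 rose and 1 fell, and a second Mcm5 probe set differed by 1.09. Of 18 cleavage and polyadenylation genes 1 rose, Cpsf4 by 1.88 (median 0.54, camera adjusted p = 0.0408, but adjusted p = 0.327 with an estimated correlation). None passed when adjusted over the list alone, and the list's call was lost without empty vector (adjusted p = 0.0909) and without D6 (0.0528). The other 14 lists had adjusted p from 0.0689 to 0.879, and none of them passed with an estimated correlation. The lowest was that of endogenous retrovirus and silencing genes (median 0.74), which passed under the authors' scaling (0.036), under median scaling (0.0326) and against hnRNP-H and D6 alone (0.0355), and NF-kB genes (median 0.34, adjusted p = 0.0968) passed without hnRNP-H (0.0414). Medians were 0.53 for class I genes, 0.44 for sterol synthesis, -0.28 for subunits of RNA polymerase II and between -0.11 and 0.08 for other hnRNP proteins, splicing, elongation, interferon, apoptosis, glycolysis and heat shock. For other hnRNP proteins (median 0.08, mean -0.03) and apoptosis (0.02 and -0.16) the test pointed down, unlike the median. Adjusted over the list alone, 3 hnRNP genes rose and 3 fell, 5 NF-kB genes rose and 3 fell, 4 sterol genes rose and 1 fell, 3 class I genes rose and 2 fell, and at most 1 passed either way in each of the others. Within the 14 lists, Psmb10 (2.27), Psmb8 (1.81), Bcl3 (2.08), Polr2a (1.68), Hmgcs1 (1.82) and Srebf1 (1.80) rose, as did Tnf, at 227 against 5.21 and 11.6 in the controls, and Hnrnpll (-1.93), Bik (-4.67), Ifi27 (-3.12), Tapbp (-1.52) and Sqle (-1.62) fell. Of these, Psmb10, Bik and Ifi27 passed with any 1 AxJ array left out, and probe sets not used differed by 0.25 for Polr2a and by -0.99 and -0.27 for Tapbp, without passing. No T cell, myeloid, erythroid or stromal marker passed, and these lists had medians of -0.24, -0.24, -0.09 and -0.09, with 0.38 for the relatives of hnRNP-F and hnRNP-H.

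hnRNP-H was set against empty vector to see how far the AxJ controls differ. The calcium-binding protein gene Pef1 read 156 against 10.6, and Pmf1, Men1, Rhog and Pld3 were higher by 2.98 to 3.20. Sycp1, a meiotic gene, read 0.789 against 75.5, and Kifc1, Prp2, Gata4 and Ces1d had differences from -2.80 to -2.72. With a pseudocount of 32 these 10 genes had differences of 1.97 to 2.26 and of -2.12 to -1.35. In all, 1651 probe sets were at least 2-fold apart, 908 higher and 743 lower in hnRNP-H, but 756 and 1022 under the authors' scaling and 750 and 1030 under median scaling. NF-kB pathway genes had a median of 0.61 (percentile 99.9), apoptosis regulators 0.35 (98.5) and interferon genes 0.41 (96.0). The Gapdh ratio was 0.866 in hnRNP-H and 0.212 in empty vector, and with 1 array each the differences have no replicate check.

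The hnRNP-F clones also differed from each other. Slc2a1, a glucose transporter gene, read 149 in D6 and 13.2 in B5, and Ap5s1, Atm, Chaf1b and Ccdc86 were higher in D6 by 2.49 to 2.91. Tmsb4x read 318 in B5 and 2.53 in D6, Igkv6-23 read 235 and 2.19, and S100a6, Ccl9 and Cd9 read 187, 97.3 and 84.2 in B5 and at most 3.76 in D6. The dimmer clone lay under 21.8 for all 10 genes, so the pseudocount sets these differences, which with a pseudocount of 32 were 1.28 to 2.01 and -3.34 to -1.74. At least 2-fold apart were 1090 probe sets, 567 higher and 523 lower in D6, but 519 and 567 under the authors' scaling and 450 and 629 under median scaling. The glycolysis and hypoxia list had a median of 0.32 (percentile 99.8). Between clone and control, the counts were 1987 for B5 against empty vector, 1269 for B5 against hnRNP-H, 1723 for D6 against empty vector and 734 for D6 against hnRNP-H, and the Gapdh ratio was 0.683 in D6 and 0.181 in B5.

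The last comparison asked whether the hnRNP-F clones moved along the difference between A20 and the AxJ controls. Across 9107 probe sets, which are not independent replicates, the 2 differences had a Pearson r of 0.309 and a Spearman rho of 0.314. Unchanged groups that share these controls gave r = 0.409 (SD 0.0116 over 100 simulated sets), and unchanged hnRNP-F clones with the observed A20 difference gave 0.195 (SD 0.01). The covariance was 0.169 against a simulated 0.106. With the controls split, so that no array was shared, r was 0.0139 and 0.0333. Without hnRNP-H as a control r was 0.519, where unchanged groups gave 0.578 (SD 0.00926) and unchanged clones with the observed A20 difference gave 0.247 (SD 0.0116), and the covariance was 0.457 against a simulated 0.156. Without empty vector r was 0.330 against 0.575 for unchanged groups, and the covariance was 0.187 against 0.153. The simulated sets gave all arrays the same spread for a probe set, and without hnRNP-H that spread came from the 2 clones alone. Empty vector stood further from all other arrays (383 probe sets) than B5 (203), hnRNP-H (82) or D6 (44). A control of larger spread would raise the covariance with nothing changed, so these simulated values cannot show a move toward A20.

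**Figure D3:**
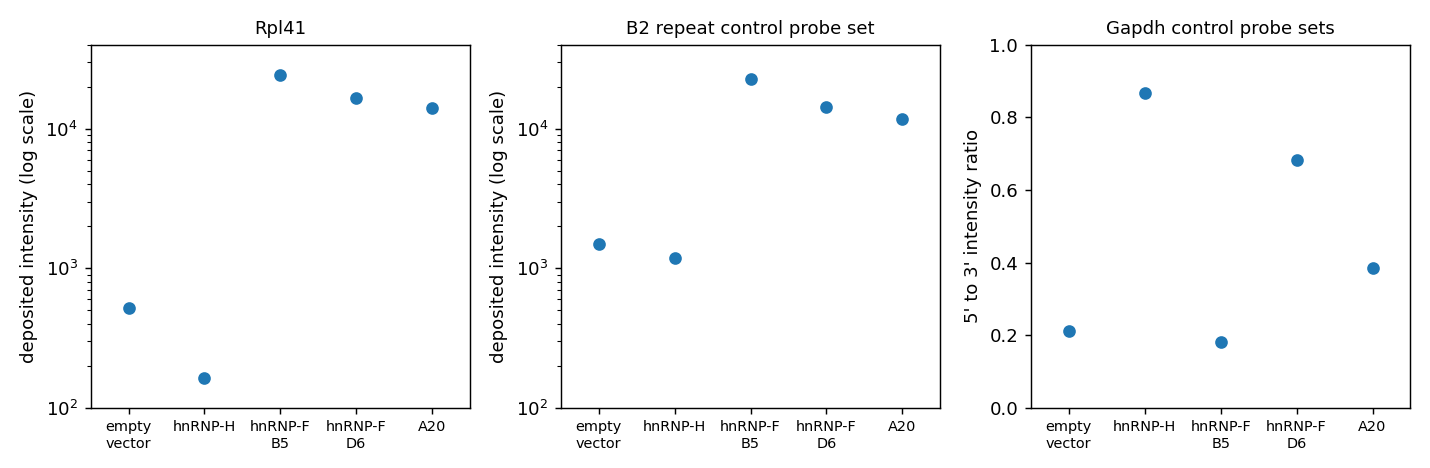
Each point is 1 array, with deposited intensity of Rpl41 and of a B2 repeat control probe set on log axes, and the 5' to 3' ratio of the Gapdh control probe sets. Rpl41 lies at 14165 or above in B5, D6 and A20 and at 518 or below in empty vector and hnRNP-H, while the Gapdh ratio is lowest in empty vector and B5.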

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

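The tests of A20, of the ribosomal proteins and of the vector for Rpl41 were chosen only after the result was seen. A maker's control probe set for the B2 repeat, which no comparison above uses, was at least 9.65-fold brighter in each hnRNP-F clone than in each AxJ control. Its deposited intensities were 1491 in empty vector, 1180 in hnRNP-H, 22650 in B5, 14385 in D6 and 11779 in A20, the same order of arrays as for Rpl41. Another control probe set named b2 did not follow it, with 2477 in empty vector, 1337 in hnRNP-H, 2125 in B5, 1239 in D6 and 603 in A20. Ribosomal protein mRNAs as a class are argued against as the explanation for Rpl41, since 38 other probe sets of this class had a median log2 difference of 0.112, with none above 1. A batch shared by empty vector and hnRNP-H may account for the pattern, but the test of A20 could not decide it. A20, which carries no hnRNP-F vector, lay 5.78 above the controls for Rpl41 (equal to the clones by quantile normalisation, but 14165 as deposited). That height was already part of the pattern, so it shows only that a high reading occurs without the vector. A batch that moves many probe sets stays open: 32 probe sets parted empty vector and hnRNP-H from the other arrays by 2-fold, while the 5 other splits of this kind gave 25 to 72. Overexpression of hnRNP-F also stays open, because both clones and neither AxJ control carry that vector. The smallest clone-to-control difference was 4.95, but Rpl41 was flagged for parting clones from controls, so this value could not decide it.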

How the results depend on the processing

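The pseudocount of 32, the Gapdh-ratio pairs and the comparison with hnRNP-H and D6 alone were chosen after seeing the data. The labels give the compared groups no shared replicate numbers, so no pairing was taken from them. A block for arrays paired by Gapdh ratio left the counts at 1 probe set for the hnRNP-F clones and 2 and 8 lists, and gave 790 probe sets for A20. For probe sets called in the hnRNP-F clones (1), the count was 0 without the filter and 0 without the intensity trend, and 0 to 3 with 1 AxJ array left out. For those called in A20 (536), it was 311, 145 and 245 to 667 in turn, and 1709 against hnRNP-H and D6 alone. Of the 536, 301 were also called without the filter and 526 against hnRNP-H and D6 alone. The fit against hnRNP-H and D6 alone took its spread from the most alike pair of arrays, which raises its count. The 83 probe sets 2-fold apart in all clone-against-control pairs became 31 with double the pseudocount, 31 above the 60th percentile, 8 with a pseudocount of 32 and 132 within both Gapdh-ratio pairs. The 926 of A20 became 597 with a pseudocount of 32 and 1476 against hnRNP-H and D6 alone. The 1651 of hnRNP-H against empty vector became 745 above the 60th percentile and 509 with a pseudocount of 32, and the 1090 of D6 against B5 became 368 and 199, and 713 with double the pseudocount. Lists passing for the hnRNP-F clones (2) were 1 without the filter, 0 with an estimated correlation and 1 to 2 with an array left out. Without B5 the lists of other hnRNP proteins and of splicing factors were both lost. The list that passed there was glycolysis and hypoxia, which was higher and had not passed before. Lists passing for A20 (8) were 0 with an estimated correlation and 7 to 9 with an array left out. Of these 8 lists, only B cell identity had an estimated correlation (0.0218) above the preset 0.01. A higher correlation therefore does not account for the loss of the other calls. In that setting camera takes its p-values from the 2 residual degrees of freedom of the fit, so few lists could pass. The correlation along the A20 difference ranged from 0.245 to 0.519 with an array left out. Other causes of these changes were not tested, except that a larger pseudocount shrinks the differences of dim probe sets and a stricter filter leaves fewer to count. Signs turned only for genes that passed in neither setting. In the hnRNP-F comparison Igha was 0.128 with the authors' scaling and 0.142 with median scaling. With 1 array left out, Igha reached from -0.64 to 0.35, Ighm from -0.69 to 1.19, Ighd from -0.21 to 0.43, Ighv1-54 from -0.0679 to 1.24, Igh-VS107 from -0.50 to 0.29, Cd4 from -0.155 to 0.52 and Dcn from -1.86 to 0.44, and in A20 Ighd from -0.52 to 0.12, Gata3 from -0.0608 to 1.36, Zap70 from -1.15 to 0.11 and Klf1 from -0.0922 to 1.15. In A20 against hnRNP-H and D6 alone, Zap70 was 0.0092 and Hba-a1 0.0097. For the 84 genes named in A20, 1279 alternative values kept sign and side of the threshold, 113 lost and 22 gained the call and 6 turned. The median of all probe sets in A20 was -0.14 under the authors' scaling and -0.10 under median scaling, against -0.04. Dim signal limits the rest, since 18.2 percent of values of kept probe sets lay under the 40th percentile in each array.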

Other observations

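Of the tests below, the correlation of array differences and the median share of A20 transcripts were set out beforehand, while the limit of 500, leaving out the genes that prompted that test, and the others were chosen only after the result was seen. Clone B5 held 6 probe sets above 100 that read at most 30 in the other AxJ lines as deposited, 1 of them with no symbol, against 2 in empty vector, 1 in hnRNP-H and 0 in D6. Among them were Igkv6-23, Rhox5 and Tmsb4x, all high in A20, and also S100a6 and S100a4, calcium-binding protein genes that read 176 and 101 in B5 and 2.02 and 3.18 in A20. These genes and the light chain gene were picked after their values were seen.

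A20 RNA or cells in the B5 sample may account for part of this, and the test compared the share in B5 of probe sets of at least 1000 in A20 and at most 30 in the other AxJ lines with the 8.64 percent of the A20 level that Igkv6-23 showed. The median share of all 6 was 3.25 percent, above the bound of 2.88 percent, so the test as set out beforehand went with A20 RNA. Of these, 3 (Igkv6-23, Rhox5 and Tmsb4x) had prompted the test. The others (Erdr1, Scd1 and Spib) had a median of 2.17 percent with an upper quartile of 2.60, below the bound. The 3 were left out for reading above 100 in B5, which lowers the share of the rest, so the median without them cannot decide against A20 RNA. At a limit of 500 the 15 others had a median of 1.775 percent with an upper quartile of 2.62, against 2.11 and 2.97 for all 18. There 4 probe sets (Spib, H2-Aa, Car2 and Timd2) stayed below 0.864 percent, with H2-Aa at 8.36 in B5 where the share of Igkv6-23 would give 78.4. For these 4, A20 RNA at the share of Igkv6-23 is argued against. A lower share stays open, since 1.775 percent lies above the upper quartiles of the other AxJ lines (-0.317, -0.192 and 0.684) while 4 of the 15 lay below 0.592 percent. Those quartiles are no neutral background. Each came from 10 probe sets that read at most 30 in B5, and B5 was part of the mean subtracted, which lowers them where B5 is raised. A probe set listed for Igkv6-23 with other kappa genes, looked up after these values were seen, showed 1.87 percent. A20 as the only source of what B5 alone showed is argued against too, since 3 of the 6 probe sets, S100a6, S100a4 and the one with no symbol (789 in B5, 3.31 in A20), lay more than 10 times lower in A20 than in B5, where another AxJ array gave at most 1 such probe set (a bound of 5, written first, was too high, since A20 material brings no transcript above its own level).

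RNA integrity or labelling may lie behind the large differences between hnRNP-H and empty vector and between D6 and B5, since the arrays with a Gapdh 5' to 3' ratio of 0.212 and 0.181 stand on one side of both. Across 9107 probe sets, these differences, which share no array, had a Pearson r of 0.102, between the bounds set beforehand for and against. B5 minus empty vector with D6 minus hnRNP-H gave 0.0977, and B5 minus hnRNP-H with D6 minus empty vector gave -0.0121. In the brighter 50 percent of probe sets r was 0.191, 0.300 and 0.0738 in turn. A shared RNA effect of this size cannot be told apart from clone differences with 1 array for each line.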
